A study of Arabidopsis thaliana with 16 samples.

How the data were processed

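RNA was measured in 16 libraries of whole Arabidopsis thaliana seedlings, 5 days old, from liquid culture. Per the labels' protocols, total RNA was turned into libraries with a TruSeq v2 kit, and MG132 was given at 100 µM in fresh medium for 3 or 24 h. The deposited files hold raw counts of reads per gene, 1 file per library with the same 33602 genes, and the values are whole numbers with no normalization. Per the submitters' processing notes, the authors used Trimmomatic, TopHat, Bowtie2, HTSeq and edgeR with the TAIR10 genome; their versions, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. The kit does not mark strand, so reads of a gene and of an overlapping or antisense partner cannot be told apart, and values of near-identical copies, such as the polyubiquitin, LHCB1 and small heat shock genes, are uncertain because reads could be split between them or dropped. The labels do not give the accession in which the mutants arose.

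Groups were taken from the labels: Col-0 untreated, 3 h and 24 h of MG132 with 4 libraries each, and rpn10-1 and rpn12a-1 with 2 each. Total counts per library ran from 6646134 to 21762565. Gene names, descriptions and coordinates come from a reference annotation of TAIR10.1, in which 32823 of the 33602 identifiers were found; it was not used to recount anything. No pair of libraries held identical values. Chi-square per degree of freedom between replicates was 7.77 to 16.5 within library sets of Col-0 and rpn12a-1, 22.4 to 59.7 across sets and 69.7 between the rpn10-1 libraries, so none was counted as a repeat of another.

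The following choices were made before the data were examined: the groups, the tests, the 19 gene lists, the rule for named genes and all alternatives except those said to be chosen later. Genes were kept by filterByExpr of edgeR with the group as factor, which left 21205, and library sizes were scaled by TMM. A negative binomial model with the group and the library set as terms was fitted to all 16 libraries, so that groups of 2 libraries shared the estimate of spread with the others. Genes were called with edgeR's quasi-likelihood F-test, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM computed from the deposited counts and scaled library sizes, given as mean and SD over libraries. The SE beside a log2 fold change was not taken from the fit itself. It is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. For fold changes near 0, above all in genes with few counts, it can be too small, so it is an approximate measure there. Where all libraries of a group held 0 counts, a fold was computed against a floor of 3 counts summed over the group, and fitted fold changes of such genes are not given. Such floors, and exact binomial intervals, cover counting error only.

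The 19 lists were the proteasome core particle, its regulatory particle, proteasome assembly and associated factors, ubiquitin with its activating enzymes, heat shock genes, the unfolded protein response of the endoplasmic reticulum, autophagy, tau glutathione transferases, photosynthesis, the cell cycle, early auxin genes, type-A cytokinin response, abscisic acid, jasmonate, salicylic acid defence, root markers, the guard cell lineage, seed storage and cytosolic ribosomal proteins. The last was defined by words in the reference's descriptions, which matched only 7 tested genes. Each list was tested against the other genes with camera of limma at a preset correlation of 0.01 and again with a correlation estimated from the data, adjusted over the 19 lists of a comparison. Fry was run as well. No list that camera called had a median, a mean and a direction of the test that differed in sign.

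For each comparison except rpn12a-1 against rpn10-1, the genes named were the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, and up to 4 members of each list with the smallest p. RPN10, RPN12A, NAC053 and NAC078 were always named, as were the 10 genes with the highest smallest rise among those higher in all 4 comparisons against untreated Col-0. The text gives a part of these, and a gene outside the rule is said to have been chosen after its values were seen.

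The pipeline was tested on simulated counts with the real means and library sizes, in which 100 genes were changed 2-fold and 100 genes 4-fold. The changed genes were drawn only from those above a minimum mean count, so recovery among genes with fewer counts was not measured. For 3 h of MG132, among 20504 genes, 63% of the former and 97% of the latter were called; for 24 h, among 20533, 72% and 99%; for rpn10-1, among 20535, 45% and 93%; and for rpn12a-1, among 20520, 42% and 91%. Between 5 and 8 unchanged genes were called in each. A change of 2-fold was thus missed in more than 50% of the mutant cases.

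Alternatives were another scaling (RLE), no filter on low counts, DESeq2, no library set term, the replicate number as a block, only the groups compared, only libraries with or without the technical replicate note, a minimum change of 2-fold and leaving out each library. Chosen after seeing the data were fits of nuclear protein-coding genes only, of genes with a mean of at least 5 CPM, of each mutant with the Col-0 libraries of the other set, of rpn10-1 placed in the other set, and counts outside chromosome blocks. The blocks were windows of 2 Mb in which changes of at least 8-fold were enriched (one-sided Fisher exact test, Benjamini-Hochberg adjusted over 62 windows). Shared controls were studied with 20 simulations of unchanged groups. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.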

Results

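Gene expression was measured by RNA sequencing of whole 5-day-old Arabidopsis thaliana seedlings grown in liquid culture under constant light. The series asks how seedlings respond when the 26S proteasome, the protease that degrades ubiquitin-tagged proteins, is blocked or weakened, and its title places this response under a pair of NAC transcription factors. Wild-type seedlings of the accession Col-0 were harvested untreated (4 libraries), after 3 h in 100 µM MG132 (4 libraries) or after 24 h in 100 µM MG132 (4 libraries). MG132 is a peptide aldehyde that inhibits the proteasome. Untreated seedlings of rpn10-1 and rpn12a-1, exon-trap mutants in subunits of the proteasome's regulatory particle, gave 2 libraries each. The 16 libraries held between 6646134 and 21762565 counts over 33602 genes, of which 21205 passed the filter on low counts and were tested. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No group was mock-treated: the untreated seedlings were harvested at once, so MG132, any solvent, the change of medium and the time since it, which at 24 h makes the seedlings older, were not separated. The labels note a technical replicate for 8 of the libraries, namely Col-0 replicates 3 and 4 of each group and both rpn12a-1 libraries. Libraries with and without that note are called library sets here, and the set was a term of the model.

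RPN10 (AT4G38630; chromosome 4, 18056988 to 18059598, minus strand, TAIR10.1), the mutated gene of rpn10-1, encodes a subunit that binds ubiquitin chains. It stood at 126, 136, 101 and 98.6 CPM (counts scaled to library size) in the untreated Col-0 libraries and at 21.4 and 22.2 CPM in the rpn10-1 libraries. It fell by 2.42 on the log2 scale (SE 0.18, edgeR adjusted p = 3.4e-07). RPN12A (AT1G64520; chromosome 1, 23956269 to 23958461, plus strand) encodes a subunit of the lid of the regulatory particle. It stood at 85.4 ± 13.8 CPM (SD, n = 4) in untreated Col-0 and at 52 and 42.9 CPM in the rpn12a-1 libraries, and fell by 0.71 (SE 0.17, edgeR adjusted p = 0.023). Each gene was higher in the mutant of the other: RPN10 at 335 ± 7.43 CPM (SD, n = 2) in rpn12a-1 and RPN12A at 166 ± 1.7 CPM (SD, n = 2) in rpn10-1. Both rose under MG132, RPN10 to 312 ± 28.3 CPM at 3 h and 309 ± 28.1 CPM at 24 h, RPN12A to 274 ± 34.5 and 388 ± 65.2 CPM (SD, n = 4 each). The NAC genes NAC053 (AT3G10500; chromosome 3, 3271217 to 3274176, plus strand) and NAC078 (AT5G04410; chromosome 5, 1243684 to 1246684, plus strand) encode transcription factors bound to membranes and reported to control proteasome genes. NAC053 rose from 16.2 ± 1.46 CPM to 40 ± 11.7 CPM at 3 h (SD, n = 4 each; edgeR adjusted p = 0.00035) and stood at 28.7 ± 6.67 CPM at 24 h (edgeR adjusted p = 0.0069). NAC078 rose from 61.5 ± 2.63 CPM to 98.8 ± 5.73 CPM at 3 h and 78.2 ± 9.12 CPM at 24 h (SD, n = 4 each; edgeR adjusted p = 0.00012 and 0.014). Neither was called in a mutant: the log2 fold changes in rpn10-1 were -0.01 ± 0.25 for NAC053 and -0.10 ± 0.12 for NAC078, and in rpn12a-1 -0.02 ± 0.25 and 0.09 ± 0.12 (SE; edgeR adjusted p from 0.58 to 0.99).

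**Figure D1:**
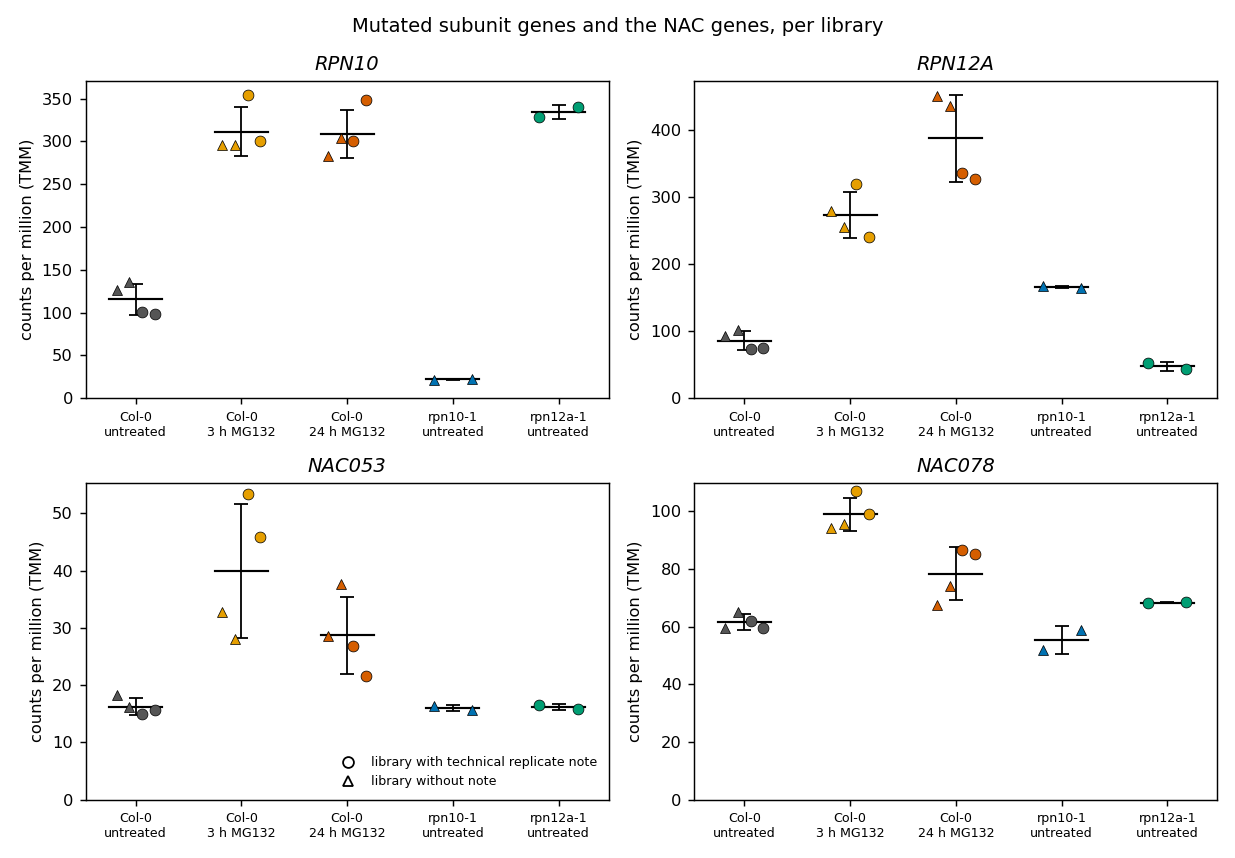
CPM (y axis, linear, from 0) of RPN10, RPN12A, NAC053 and NAC078 in each of the 16 libraries, by group; circles are libraries with the technical replicate note, triangles those without, and bars give the group mean and SD. RPN10 lies at 21.4 and 22.2 CPM in the rpn10-1 libraries against 98.6 to 136 CPM in the untreated Col-0 libraries.

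The first comparison asked what changed within 3 h of MG132. Beside the counts of list members called among all genes, counts adjusted over the list alone are given in brackets wherever they differed. Genes for the proteasome itself, for ubiquitin and for heat shock proteins rose together, while cytokinin response genes fell. All 24 tested genes of the core particle, the barrel that holds the proteolytic sites, rose, with a median log2 fold change of 1.5. CDC48D, a form of the ATPase that unfolds ubiquitinated proteins, rose from 18.6 ± 1.46 to 468 ± 148 CPM, and the polyubiquitin gene UBQ10 from 1350 ± 81.2 to 5530 ± 1650 CPM (SD, n = 4 each). The cytosolic chaperone gene HSP90-1 rose from 13.5 ± 5.1 to 483 ± 196 CPM (SD, n = 4 each).

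In the core particle list, PAA2 (AT2G05840), an alpha subunit, rose by a log2 fold change of 2.46 ± 0.13, and PBE2, a catalytic beta subunit, by 2.42 ± 0.11 (SE; edgeR adjusted p = 6.9e-09 and 1.5e-09). Of 32 regulatory particle genes, 27 rose and none fell (28 rose when adjusted over the list alone), led by the ATPase gene RPT6B from 33.8 ± 5.65 to 358 ± 64 CPM (SD, n = 4 each). Of 23 genes for assembly chaperones, CDC48 and other factors that act with the proteasome, 14 rose (18 adjusted over the list alone), among them the assembly chaperones NAS6 (2.53 ± 0.13) and UMP1A (1.75 ± 0.13; log2 fold change and SE). Of 8 genes for ubiquitin and its activating enzyme, 7 rose, by all genes and adjusted over the list alone. These lists stood apart from the other genes (camera adjusted p = 5.13e-96, 2.74e-66, 4.48e-27 and 9.98e-13 in that order; 0.000668, 0.00195, 0.00228 and 0.0102 with an estimated correlation).

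Of 34 heat shock genes, 26 rose and 1 fell (28 and 1 adjusted over the list alone), with a median log2 fold change of 2.85 (camera adjusted p = 4.86e-76; 4.65e-05 with an estimated correlation). The disaggregase HSP101 rose by 2.71 ± 0.11 and the mitochondrial small heat shock gene HSP23.6 by 5.66 ± 0.24 (log2 fold change and SE). Of 25 tau-class glutathione transferase genes, which encode enzymes that conjugate glutathione to foreign or oxidised compounds, 12 rose and 2 fell (14 and 3 adjusted over the list alone; camera adjusted p = 1.17e-08, and 0.0468 with an estimated correlation). GSTU22 rose from 1.22 ± 0.509 to 97.3 ± 24 CPM (SD, n = 4 each). Of 12 cytokinin genes, mostly the type-A response regulators that cytokinin induces, 11 fell (12 adjusted over the list alone), with a median of -1.06 (camera adjusted p = 1.2e-08; 0.00878 with an estimated correlation). ARR5 fell by 1.6 (SE 0.18). Of 19 early auxin genes 10 fell (11 adjusted over the list alone; camera adjusted p = 0.000139, and adjusted p = 0.187 with an estimated correlation). Among them was the auxin repressor gene IAA29, which fell by 1.66 (SE 0.25). Of 17 abscisic acid genes 6 rose (9 adjusted over the list alone), such as the cold-induced COR6.6 from 48 ± 11.1 to 189 ± 110 CPM (SD, n = 4 each; camera adjusted p = 0.00746, and 0.487 with an estimated correlation).

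Of 32 autophagy genes 7 rose and 1 fell at 3 h (7 and 2 adjusted over the list alone; camera adjusted p = 0.00972 and adjusted p = 0.297 with an estimated correlation). NBR1, a receptor that carries ubiquitinated cargo to the vacuole, rose from 191 ± 16.5 to 736 ± 184 CPM (SD, n = 4 each). The ubiquitin-like ATG8F fell from 82.4 ± 10 to 48.1 ± 5.17 CPM (SD, n = 4 each). Of 39 photosynthesis genes 3 fell (2 adjusted over the list alone; camera adjusted p = 0.00151 and adjusted p = 0.658 with an estimated correlation). Of 25 cell cycle genes none was called although the list was (camera adjusted p = 0.00746; adjusted p = 0.487 with an estimated correlation). Of 8 guard cell lineage genes 2 fell (4 adjusted over the list alone; camera adjusted p = 0.0186 and adjusted p = 0.298 with an estimated correlation). Only 2 of 19 genes of the unfolded protein response of the endoplasmic reticulum rose, the transcription factor gene BZIP60 (1.73 ± 0.14) and the chaperone gene ERDJ3A (1.77 ± 0.18; log2 fold change and SE). That list was not called (camera adjusted p = 0.0687). Single genes rose in the jasmonate list (LOX4 of 19, and 0 adjusted over the list alone), the salicylic acid defence list (PAD3 of 20) and the root marker list (IRT1 of 16). SESA4 fell among 7 seed storage genes, and 2 of 7 cytosolic ribosomal protein genes rose (2 higher and 1 lower adjusted over the list alone). None of these lists was called, with camera adjusted p of 0.936, 0.748, 0.936, 0.936 and 0.602.

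Outside these lists, rises included those of the cytochrome P450 gene CYP89A3, from 0.0932 ± 0.082 to 16.5 ± 4.6 CPM, and of PMZ, which encodes an AN1-type zinc finger protein, from 0.921 ± 0.216 to 106 ± 15.2 CPM (SD, n = 4 each). ILL5, for a putative auxin conjugate hydrolase, had 1 count over the untreated Col-0 libraries and 5.03 ± 1.44 CPM at 3 h (SD, n = 4). The falls were smaller. SPX1, a sensor of phosphate status, fell from 156 ± 91 to 21.1 ± 14.3 CPM (SD, n = 4 each). CER4, which makes primary alcohols of the leaf wax, fell from 6.1 ± 3.73 to 0.711 ± 0.418 CPM, and the acyltransferase gene AT5G47980 from 21.6 ± 16.4 to 2.11 ± 0.678 CPM (SD, n = 4 each). In all, 3800 of 21205 genes were called, 1841 higher and 1959 lower, and 1358 changed at least 2-fold. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Fitted within the library sets, 1228 genes were called from the libraries without the technical replicate note and 4229 from those with it.

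After 24 h in MG132 proteasome genes were again higher than in untreated seedlings, genes of salicylic acid defence and of the unfolded protein response had joined them, and photosynthesis genes were lower. With an estimated correlation the unfolded protein response and photosynthesis lists were not called (adjusted p = 0.09 and 0.202). All 24 core particle genes rose (24 adjusted over the list alone), with a median log2 fold change of 2.08; PAA2 (AT2G05840) reached 957 ± 133 CPM from 74.7 ± 8.73 CPM (SD, n = 4 each). Of 20 salicylic acid defence genes 18 rose (19 adjusted over the list alone), among them WRKY70, a transcription factor of that pathway, from 2.68 ± 0.682 to 53 ± 27.8 CPM (SD, n = 4 each). Of 39 photosynthesis genes 37 fell (38 adjusted over the list alone), including the antenna protein gene LHCB1.4 from 2880 ± 539 to 706 ± 109 CPM (SD, n = 4 each).

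Of the 32 regulatory particle genes 28 rose, with a median of 1.55, and of the 23 associated factors 17 rose, with a median of 1.25. RPT6B reached 425 ± 18.6 CPM, RPN7 563 ± 36.5 CPM from 147 ± 21.5 CPM, and the deubiquitinase gene UBP7 50.6 ± 3.74 CPM from 12.5 ± 1.17 CPM (SD, n = 4 each). The core, regulatory and associated lists were called (camera adjusted p = 1.71e-134, 4.92e-69 and 2.12e-34; 0.000276, 0.00141 and 0.00141 with an estimated correlation). The ubiquitin list, with 3 of 8 genes higher, was not (camera adjusted p = 0.197). The salicylic acid list had a median of 3.06 (camera adjusted p = 6.33e-28; 0.00678 with an estimated correlation). PBS3, which conjugates isochorismate in salicylic acid synthesis, reached 37.1 ± 16.8 CPM and the defence-induced kinase gene FRK1 11.2 ± 4.17 CPM (SD, n = 4 each). The antimicrobial protein gene PR1, with 3 counts over the untreated Col-0 libraries, reached 172 ± 169 CPM (SD, n = 4).

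Of 19 unfolded protein response genes 18 rose, with a median of 0.81 (camera adjusted p = 4.66e-11; adjusted p = 0.09 with an estimated correlation). The disulfide isomerase PDIL1-2 rose by 1.56 ± 0.18 and the calreticulin CRT3 by 1.6 ± 0.23 (log2 fold change and SE). Of 32 autophagy genes 14 rose (15 adjusted over the list alone; camera adjusted p = 2.86e-06, and adjusted p = 0.0697 with an estimated correlation). NBR1 stood at 1490 ± 195 CPM and the kinase gene ATG1A at 84.8 ± 26.4 CPM from 25.9 ± 3.43 CPM (SD, n = 4 each). Of 34 heat shock genes 16 were higher and 3 lower than in untreated seedlings (16 and 4 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 2.13e-05; adjusted p = 0.127 with an estimated correlation). The tau glutathione transferases were 10 higher and 3 lower of 25 (camera adjusted p = 0.0465; adjusted p = 0.47 with an estimated correlation).

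The photosynthesis list had a median of -0.90 (camera adjusted p = 3.14e-17; adjusted p = 0.202 with an estimated correlation). Early auxin genes were lower in 9 of 19 cases (11 adjusted over the list alone; camera adjusted p = 0.000292, and adjusted p = 0.202 with an estimated correlation). Of 16 root markers 5 fell, among them LRX1 and PRP3, cell wall protein genes of root hairs. The median was -1.02 (camera adjusted p = 0.00586; adjusted p = 0.47 with an estimated correlation). Of 19 jasmonate genes 5 fell, including MYC2, the master transcription factor of that response, by 1.36 (SE 0.25). For that list camera's adjusted p was 0.0377, and adjusted p = 0.458 with an estimated correlation. No cell cycle gene of 25 was called, and the list's median and mean differed in sign (camera adjusted p = 0.923). Of 12 cytokinin genes 1 rose and 1 fell, and of 17 abscisic acid genes 3 fell (camera adjusted p = 0.237 and 0.0736). The guard cell lineage (1 of 8 lower), seed storage (2 of 7 lower) and ribosomal protein lists (1 of 7 lower) were not called either (camera adjusted p = 0.116, 0.058 and 0.825), though without the library set term seed storage was (0.0338). Adjusted over the list alone 0 guard cell and 0 ribosomal genes were lower.

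Outside the lists, WAK3, a wall-associated receptor kinase gene, was at 0 in all untreated Col-0 libraries and at 14.5 ± 7.11 CPM (SD, n = 4) at 24 h. It was at least 242-fold higher, against a floor of 3 counts over the group. CYP89A3 reached 60 ± 15.1 CPM and the natriuretic peptide gene PNP-A 198 ± 179 CPM from 0.244 ± 0.22 CPM (SD, n = 4 each). Falls included AT1G29090, from 14.8 ± 7.94 to 0.301 ± 0.14 CPM (SD, n = 4 each). AIR1, an auxin-induced gene of roots, fell from 63.8 ± 24.9 to 2.5 ± 2.12 CPM and MRN1, for the triterpene enzyme marneral synthase, from 21.8 ± 9 to 1.35 ± 0.498 CPM (SD, n = 4 each). In all, 5595 genes were called (2673 higher, 2922 lower), 2040 of them changed at least 2-fold. Within the library sets the count was 5321 without the technical replicate note and 3633 with it.

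The 24 h and 3 h groups were then compared directly. Heat shock and ubiquitin genes were lower at 24 h than at 3 h, while core particle, salicylic acid and cytokinin genes were higher. Of these lists, the core particle's was not called with an estimated correlation (adjusted p = 0.0741). Of 34 heat shock genes 26 fell (30 fell and 1 rose adjusted over the list alone), with a median of -2.16 (camera adjusted p = 3.33e-57; 0.000136 with an estimated correlation). HSFA2, a heat shock transcription factor gene, fell from 45.9 ± 6.93 to 2.97 ± 1.08 CPM, and HSP23.6 from 71.9 ± 16.8 to 1.26 ± 0.729 CPM (SD, n = 4 each). UBQ10 fell from 5530 ± 1650 to 1870 ± 105 CPM (SD, n = 4 each). In total, 5 of 8 ubiquitin genes fell (camera adjusted p = 6.24e-10; 0.0394 with an estimated correlation). Of the 20 salicylic acid genes 18 rose (19 adjusted over the list alone; camera adjusted p = 1.13e-37, and 0.00452 with an estimated correlation).

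Of the 24 core particle genes 20 were higher at 24 h (22 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 2.02e-18; adjusted p = 0.0741 with an estimated correlation). The regulatory list had 7 of 32 higher (9 adjusted over the list alone; camera adjusted p = 0.000931 and adjusted p = 0.364 with an estimated correlation). The associated factors had 7 higher and 1 lower of 23 (8 and 1 adjusted over the list alone; camera adjusted p = 0.000652 and adjusted p = 0.24 with an estimated correlation). Cytokinin genes rose in 7 of 12 cases (9 adjusted over the list alone; camera adjusted p = 2.74e-06, and 0.0394 with an estimated correlation). ARR16 rose by 1.64 ± 0.21 (log2 fold change and SE). Of 19 unfolded protein response genes 14 rose and 1 fell (15 and 2 adjusted over the list alone; camera adjusted p = 2.33e-09 and adjusted p = 0.13 with an estimated correlation). Of 39 photosynthesis genes 18 fell (30 adjusted over the list alone; camera adjusted p = 5.74e-12, and adjusted p = 0.24 with an estimated correlation). Of 17 abscisic acid genes 7 fell (8 adjusted over the list alone; camera adjusted p = 4.83e-07 and adjusted p = 0.197 with an estimated correlation). COR15A, which protects membranes in the cold, fell by 4.81 (SE 0.53).

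Called between 24 h and 3 h were also the lists of tau glutathione transferases (1 higher and 8 lower of 25), autophagy (5 of 32 higher), cell cycle (4 of 25 higher), jasmonate (4 of 19 lower), root marker (2 of 16 lower) and seed storage genes (2 of 7 lower). Adjusted over the list alone these were 2 and 12, 5, 5, 6, 2 and 5 genes. Their camera adjusted p were 7.34e-05, 0.00297, 0.00394, 0.00704, 0.000329 and 0.00704; with an estimated correlation the adjusted p were 0.193, 0.234, 0.361, 0.24, 0.323 and 0.24. Of 19 early auxin genes 3 rose and 1 fell (3 and 2 adjusted over the list alone). No guard cell or ribosomal gene was called (1 ribosomal gene higher and 2 lower adjusted over the list alone). These lists were not called (camera adjusted p = 0.781, 0.52 and 0.297). AT3G28510, for a P-loop nucleoside triphosphate hydrolase, was at 0 in all 3 h libraries and at 44.1 ± 42.5 CPM (SD, n = 4) at 24 h, at least 517-fold higher against a floor of 3 counts over the group. The defence gene LURP1 rose from 0.207 ± 0.34 to 154 ± 102 CPM, the U-box gene PUB54 from 0.0355 ± 0.071 to 28.4 ± 18.3 CPM and PR1 from 0.243 ± 0.238 to 172 ± 169 CPM (SD, n = 4 each). Among the falls was that of the auxin glucosyltransferase gene UGT74E2, from 99.5 ± 33.8 to 1.64 ± 0.984 CPM (SD, n = 4 each). NAC078 was lower at 24 h than at 3 h (fell by 0.34, SE 0.09, edgeR adjusted p = 0.022), while NAC053, at -0.47 ± 0.19 (SE), did not pass the test (edgeR adjusted p = 0.11). In all, 3398 genes were called (1753 higher, 1645 lower), 1346 of them changed at least 2-fold; 5469 were called without and 1923 with the technical replicate note. Without 1 library the count fell to 2185 (without 3 h replicate 2), 2008 (without 24 h replicate 1) or 2119 (without 24 h replicate 2).

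**Figure D2:**
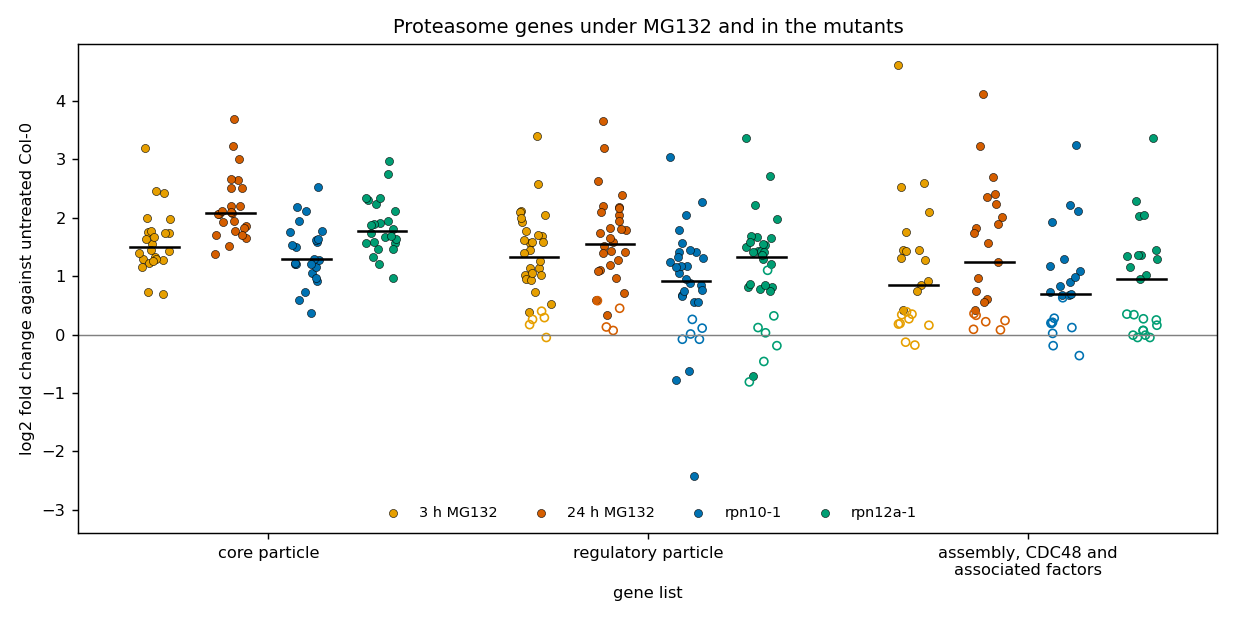
Log2 fold change against untreated Col-0 (y axis) of each tested gene of the core particle (24), regulatory particle (32) and associated factor (23) lists under 3 h and 24 h of MG132 and in both mutants; filled points were called, open points were not, and bars are medians. The core particle medians are 1.5, 2.08, 1.28 and 1.77, and the lowest point is RPN10 in rpn10-1, at -2.42.

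In rpn10-1, untreated, genes for the proteasome were higher than in Col-0, 4 of 8 stomatal lineage genes and 6 of 25 cell cycle genes were lower, and some genes on no list were at 0 in Col-0 or in the mutant. With an estimated correlation these lists were not called (adjusted p = 0.525 and 0.883). All 24 core particle genes rose (24 adjusted over the list alone), with a median of 1.28 (camera adjusted p = 1.83e-47; 0.0252 with an estimated correlation). CDC48D rose to 160 ± 32 CPM and RPT6B to 275 ± 5.21 CPM (SD, n = 2 each). TMM, a receptor that patterns stomata, fell from 19.5 ± 1.62 CPM (SD, n = 4) to 4.41 ± 2.85 CPM (SD, n = 2).

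Of 32 regulatory particle genes 24 rose and 3 fell, RPN10 itself among the latter (camera adjusted p = 4.32e-17; adjusted p = 0.146 with an estimated correlation). Of 23 associated factors 14 rose (15 rose and 1 fell adjusted over the list alone; camera adjusted p = 4.33e-11 and adjusted p = 0.0872 with an estimated correlation). NAS6 rose by 2.11 ± 0.16 and HSM3, another assembly chaperone, by 2.22 ± 0.23 (log2 fold change and SE). Of 8 guard cell lineage genes 4 fell, with a median of -1.05 (camera adjusted p = 0.0222; adjusted p = 0.525 with an estimated correlation). The peptide gene EPF2 fell by 2.19 (SE 0.44). Of 25 cell cycle genes 6 fell (8 adjusted over the list alone; camera adjusted p = 0.0222, and adjusted p = 0.883 with an estimated correlation), and without the library set term the list was not called (camera adjusted p = 0.0534). KN, a syntaxin gene of the cell plate, fell by 1.3 (SE 0.27). Of 39 photosynthesis genes 4 fell (3 adjusted over the list alone; camera adjusted p = 0.033 and adjusted p = 0.967 with an estimated correlation). No other list was called. Of 8 ubiquitin genes 2 rose, and of 34 heat shock genes 5 rose and 2 fell. None of 19 unfolded protein response genes and none of 16 root markers was called. Autophagy had 3 higher and 2 lower of 32, tau glutathione transferases 5 and 4 of 25, abscisic acid 3 and 1 of 17, jasmonate 3 and 3 of 19 and salicylic acid 1 and 1 of 20. Cytokinin had 1 higher and 4 lower of 12, and auxin and ribosomal proteins 1 lower each, of 19 and 7. Adjusted over the list alone the counts were 6 and 5 for the tau glutathione transferases, 4 and 3 for abscisic acid, 4 and 3 for jasmonate, and 0 for auxin and ribosomal proteins. The jasmonate-induced storage gene VSP1 fell by 5.26 (SE 0.64) and the defence transcription factor gene WRKY38 rose by 4.93 ± 0.71 (SE). VSP2, next to VSP1 by locus number, fell by 4.81 (SE 0.63). It lies in a window of chromosome 5 (8 to 10 Mb) that was enriched in changes of at least 8-fold in rpn10-1. In that window AT5G24735 and AT5G26270 were at 0 in both rpn10-1 libraries. The falls of both VSP genes thus cannot be told apart from absent genes or reads that do not map. Of 7 seed storage genes 4 rose (4 rose and 1 fell adjusted over the list alone). They differed between the rpn10-1 libraries: CRU3, a cruciferin, stood at 16.1 ± 21.9 CPM and OLEO1, an oleosin, at 3.58 ± 4.68 CPM (SD, n = 2 each). Without replicate 2 the log2 fold change of OLEO1 was -0.46 in place of 3.17. Against the Col-0 libraries of either set alone 4 seed storage genes were tested and none was called.

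The genes with the largest changes belonged to no list. AT1G54040, annotated as epithiospecifier protein, a factor of glucosinolate breakdown, rose from 2.99 ± 1.09 CPM (SD, n = 4) to 3840 ± 465 CPM (SD, n = 2). Under MG132 it did not rise (log2 fold changes of -0.41 at 3 h and -1.59 at 24 h). The labels do not give the accession of the mutants, so a difference between accessions was not told apart from an effect of the mutation. AT1G63540 and AT4G22450 were at 0 in all untreated Col-0 libraries and at least 285-fold and 321-fold higher in rpn10-1, against a floor of 3 counts over the group. In the other direction CYP705A5, THAS1 and AT5G47980, which lie close together on chromosome 5 (19428888 to 19461706, TAIR10.1) and belong to the cluster that makes the root triterpene thalianol, were at 0 in both rpn10-1 libraries. They were at least 1540-fold, 790-fold and 185-fold lower than in untreated Col-0, against a floor of 3 counts over the group, while CYP708A2, which lies between CYP705A5 and THAS1 and was looked up after these values were seen, fell by 2.12. In 62 windows of 2 Mb, 12 were enriched in changes of at least 8-fold (one-sided Fisher exact test, adjusted over windows). These held 224 of 537 such changes (41.7%) and 15.5% of the tested genes, and lay on chromosomes 1, 2, 4 and 5. The densest, chromosome 2 from 2 to 4 Mb, held 26 of the 224 in 109 tested genes, and all 26 were higher in rpn10-1. Why this window differed was not tested. The thalianol genes lie in an enriched window (chromosome 5, 18 to 20 Mb), as does AT1G63540 (chromosome 1, 22 to 24 Mb). In such windows a count of 0 cannot tell a silent gene from one that is absent or whose reads do not map. The folds against the floor carry the same limit. In all, 4873 genes were called in rpn10-1 (2427 higher, 2446 lower), 2575 of them changed at least 2-fold.

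The count for rpn10-1 rested on the control libraries it was set against. With the Col-0 libraries of its own set it was 5220, with those carrying the technical replicate note 1854, and 1511 genes (612 higher, 899 lower) were called the same way in both fits, against 2 called in opposite ways. Without 1 library it fell to 2235 (without rpn10-1 replicate 1), 3217 (without Col-0 replicate 1) or 3076 (without Col-0 replicate 2). The rpn10-1 libraries also stood apart: 27992 genes had a count in replicate 1, against 22120 to 24001 in the other libraries. In turn 7.41% of the counts of replicate 2 came from organelle genes and ribosomal RNA, against 0.131% to 3.07% in the others. Against the control libraries of its own set 23 core and 23 regulatory particle genes were higher, and against those of the other set 24 and 24. For the core list adjusted p = 0.0942 and 0.179 with an estimated correlation in these fits. At the preset correlation the cell cycle list was called in neither fit (camera adjusted p = 0.249 and 0.0575). The guard cell and photosynthesis lists were not called against the rpn10-1 library set's own controls (camera adjusted p = 0.189 and 0.136). Against those of the other set they were (camera adjusted p = 0.0375 and 0.0461).

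In rpn12a-1, untreated, the proteasome genes were again higher, and few genes of other lists moved. All 24 core particle genes rose (24 adjusted over the list alone), with a median of 1.77 (camera adjusted p = 1.3e-166; 8.33e-05 with an estimated correlation). PBB2, a catalytic beta subunit, rose from 48.5 ± 8.73 CPM (SD, n = 4) to 225 ± 12.9 CPM (SD, n = 2). Of 32 regulatory particle genes 24 rose and 1, RPN12A itself, fell (26 and 3 adjusted over the list alone), and of 23 associated factors 12 rose (13 adjusted over the list alone). RPT6B stood at 350 ± 28.7 CPM and CDC48D at 214 ± 16.5 CPM (SD, n = 2 each). LOX2, a lipoxygenase that starts jasmonate synthesis in chloroplasts, fell from 179 ± 65.7 CPM (SD, n = 4) to 20.9 ± 2.7 CPM (SD, n = 2).

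The regulatory and associated lists had medians of 1.33 and 0.95 (camera adjusted p = 6.66e-60 and 5.41e-26; 0.00318 each with an estimated correlation). Of 34 heat shock genes 5 fell (7 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 3.31e-06; adjusted p = 0.151 with an estimated correlation). HSP70-4, a cytosolic chaperone gene, fell by 1.77 (SE 0.31). With the replicate number as a block the heat shock list was not called (camera adjusted p = 0.193). The same held for the salicylic acid list, of which 4 of 20 genes rose (camera adjusted p = 0.00584 without the block and 0.72 with it; adjusted p = 0.583 with an estimated correlation). Without the library set term it was not called either (camera adjusted p = 0.173). The cell cycle and cytokinin lists, with no member called, passed camera's test at 0.00584 and 0.0127 (adjusted p = 0.583 and 0.351 with an estimated correlation). The other lists did not. No ubiquitin, unfolded protein response, root marker, seed storage or ribosomal gene was called. Autophagy had 1 of 32 higher (NBR1, by 0.91 ± 0.21, SE) and auxin 1 of 19. Lower were 1 of 25 tau glutathione transferases, 3 of 17 abscisic acid genes and 1 of 8 guard cell genes. Photosynthesis had 1 higher and 1 lower of 39 and jasmonate 2 and 2 of 19. Adjusted over the list alone the counts were 2 for autophagy, 4 and 4 for jasmonate and 2 for guard cell lineage. The block added the auxin and guard cell lists (camera adjusted p = 0.0346 each). With the Col-0 libraries of its own set alone, the core, regulatory and associated lists were not called with an estimated correlation (camera adjusted p = 0.0564, 0.0609 and 0.0564). With those of the other set alone, the core and associated lists were called and the regulatory list was not (camera adjusted p = 0.0327, 0.0327 and 0.116). All 24 core particle genes were higher in both fits.

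As in rpn10-1, AT1G54040 rose, to 2640 ± 107 CPM, and the defensin-like gene AT1G34047 rose from 0.431 ± 0.0387 CPM (SD, n = 4) to 228 ± 119 CPM (SD, n = 2). AT4G22450, AT1G63540, AT1G61510 and AT1G42110 were at 0 in the untreated Col-0 libraries and at least 297-fold, 148-fold, 146-fold and 114-fold higher. AT1G72840, a disease resistance gene of the TIR-NBS-LRR class, was at 0 in both rpn12a-1 libraries and at least 163-fold lower than in untreated Col-0, as was AT1G64270 (198-fold), each against a floor of 3 counts over the group. Of 62 windows 7 were enriched in changes of at least 8-fold, holding 82 of 185 (44.3%) and 9.12% of the tested genes. RPN12A lay in an enriched window (chromosome 1, 22 to 24 Mb), together with AT1G63540, AT1G61510 and AT1G64270. AT1G72840 lay in another (chromosome 1, 26 to 28 Mb). The limit on counts of 0 given for rpn10-1 holds for these genes too. AT1G54040 lay in a further enriched window (chromosome 1, 20 to 22 Mb), and the limit on accession given for it in rpn10-1 holds here. In all, 1039 genes were called (559 higher, 480 lower), 728 of them changed at least 2-fold, and 2124 with the replicate number as a block. With the Col-0 libraries of its own set the count was 1389 and with those without the note 4598. In both fits 1027 genes (528 higher, 499 lower) were called the same way, against 8 called in opposite ways. Without rpn12a-1 replicate 1 the count was 564 and without replicate 2 it was 495.

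**Figure D3:**
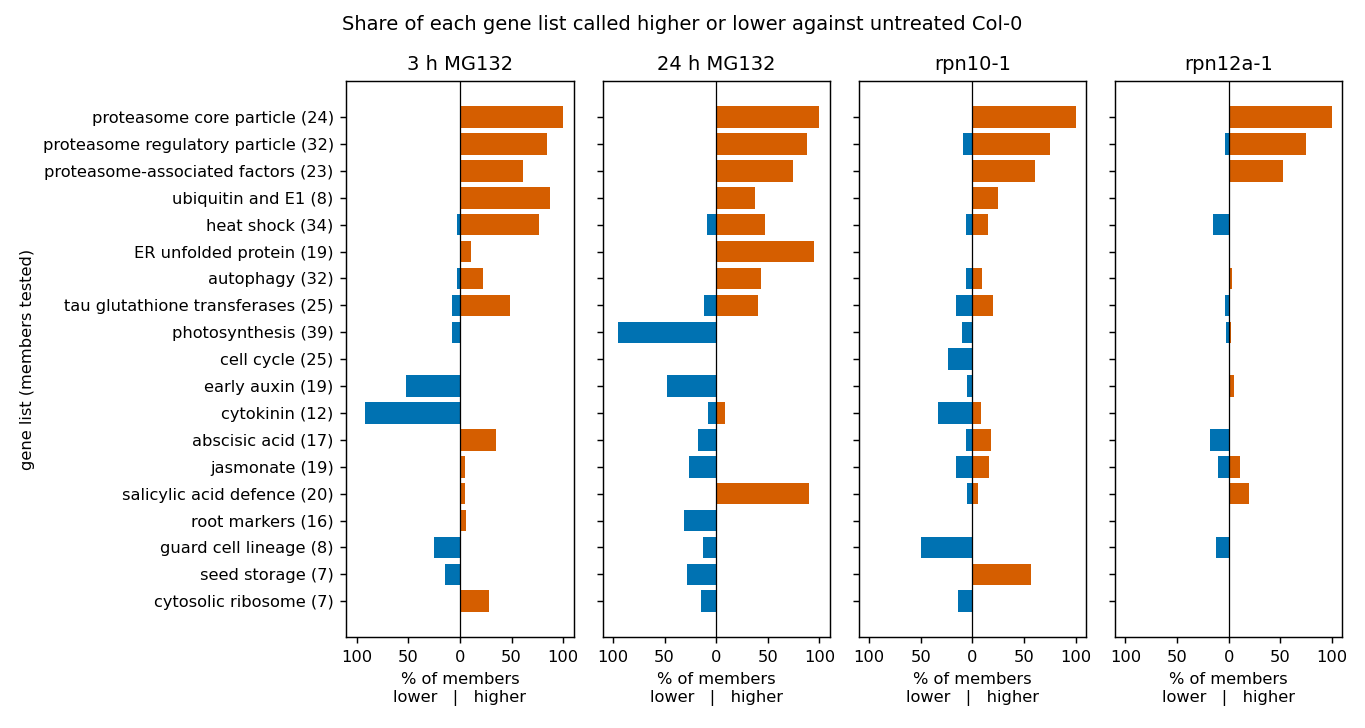
Percent of the tested members of each of the 19 gene lists (y axis, number tested in brackets) called higher (orange, to the right) or lower (blue, to the left) against untreated Col-0, for 3 h and 24 h of MG132, rpn10-1 and rpn12a-1. The core particle list reaches 100% higher in all 4 comparisons, and photosynthesis is lower for 37 of 39 genes at 24 h of MG132.

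Set against each other, the mutants differed in the subunit genes themselves, RPN10 being higher in rpn12a-1 by 3.97 ± 0.22 and RPN12A lower by 1.56 (log2 fold change, SE 0.21; edgeR adjusted p = 5.5e-08 and 0.00044). Of 24 core particle genes 6 were higher in rpn12a-1 (15 adjusted over the list alone), with a median of 0.46. Of 34 heat shock genes 7 were lower (8 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 3.37e-06 and 0.000113; adjusted p = 0.93 for each with an estimated correlation). The heat shock list was not called with the replicate number as a block (camera adjusted p = 0.106) or without the library set term (0.0858), and the early auxin list then was (0.00768 and 0.0069). The regulatory particle list had 1 higher and 1 lower of 32 (camera adjusted p = 0.00721; adjusted p = 0.93 with an estimated correlation), and no other list was called. Of 21205 genes 1338 differed (816 higher and 522 lower in rpn12a-1), 996 by at least 2-fold. As the mutants lie in different library sets, this comparison has no value within a set. It gave 261 genes from these 4 libraries alone and 782 without the set term. Leaving out rpn10-1 replicate 1 gave 804, rpn12a-1 replicate 1 gave 521, rpn12a-1 replicate 2 gave 478 and 24 h replicate 1 gave 2045.

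The last question was which genes moved alike when the proteasome was inhibited and when a subunit was mutated. A set of 174 genes was higher in all 4 comparisons against untreated Col-0, and 52 were lower in all 4. All 24 core particle genes, 22 of 32 regulatory particle genes and 12 of 23 associated factors were among the 174, where 0.197, 0.263 and 0.189 were expected (Fisher's exact test, adjusted p = 3.2e-50, 1.9e-38 and 5e-19). As every core gene had been called higher in each comparison, the test of that list adds nothing to those calls. The p-values also treat genes as independent, which these were not (estimated correlation 0.52, 0.408 and 0.212 at 3 h), so they are too small. Of the other 16 lists, 1 gene was among the 174, NBR1. Outside the lists, PMZ had the highest smallest rise, with log2 fold changes of 6.86 at 3 h, 7.51 at 24 h, 6.17 in rpn10-1 and 6.18 in rpn12a-1. The transcription factor gene NAC103, known from the unfolded protein response, rose by 3.67, 5.01, 4.72 and 5.07. SRO3, of a family of regulators of stress responses, rose by 3.35, 4.81, 4.19 and 3.65, and the uncharacterised AT5G61490 by 4.08, 5.68, 4.99 and 5.62 in the same order. Among the 52 lower genes were CYP716A2, a cytochrome P450 gene (-4.14, -2.68, -4.68 and -4.78 in that order), and LSU1, a gene induced by sulfur starvation. Others were ICS2, for an isochorismate synthase, and the cytokinin genes WOL and LOG1, a receptor and an activating enzyme. These were picked from the list after their values were seen.

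These 4 comparisons share their controls, which alone makes fold changes correlate. Across genes, which are not independent replicates, Pearson's correlation of log2 fold changes was 0.608 between 3 h and 24 h of MG132 and 0.482 between the mutants, where unchanged groups simulated against the same controls gave 0.483 and 0.202. The covariances were 0.426 and 0.461, against simulated ones of 0.0365 and 0.0248. Between MG132 and the mutants the correlations were 0.22 (3 h) and 0.275 (24 h) with rpn10-1 and 0.195 and 0.289 with rpn12a-1, below the simulated 0.378, 0.378, 0.375 and 0.398. Yet the covariances of 0.197, 0.311, 0.115 and 0.217 lay above the simulated 0.0373, 0.0364, 0.0361 and 0.0374. With the controls split between the comparisons, the correlations were 0.563 and 0.443 for the MG132 times (the 3 h group set against the libraries without and with the note) and 0.406 for the mutants. They were 0.137, 0.119, 0.166 and 0.177 for MG132 with the mutants (3 h and 24 h with rpn10-1, then with rpn12a-1). Simulated unchanged groups gave no gene higher in all 4 in any of 20 runs. But each of their comparisons called at most 1 gene higher, so these runs could not show how far shared controls raise the overlap. Independent lists of these sizes would share 0.7, a value that takes no account of shared controls. With the controls split by library set 156 and 139 genes were higher in all 4 (3 h with and without the note). Of these, 143 and 131 were among the 174. In both splits the MG132 times had different controls, as had the mutants, but each MG132 group still shared its controls with 1 mutant. Higher both at 24 h and in rpn12a-1 were 312 genes (70.5 expected from independent lists), and lower in both 169 (66.1); for rpn10-1 these were 678 (306) and 701 (337), with 83 and 271 genes called in opposite ways. At 3 h and in rpn10-1, 371 genes were higher in both (211 expected), 427 lower in both (226), and 303 called in opposite ways. With the controls split, these overlaps were weaker for rpn10-1. At 24 h 335 genes were then higher in both (213 expected), 307 lower in both (238) and 459 called in opposite ways, and at 3 h 354 (249), 370 (279) and 493. For 24 h and rpn12a-1 they were 295 (83.8), 154 (91.1) and 144.

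**Figure D4:**
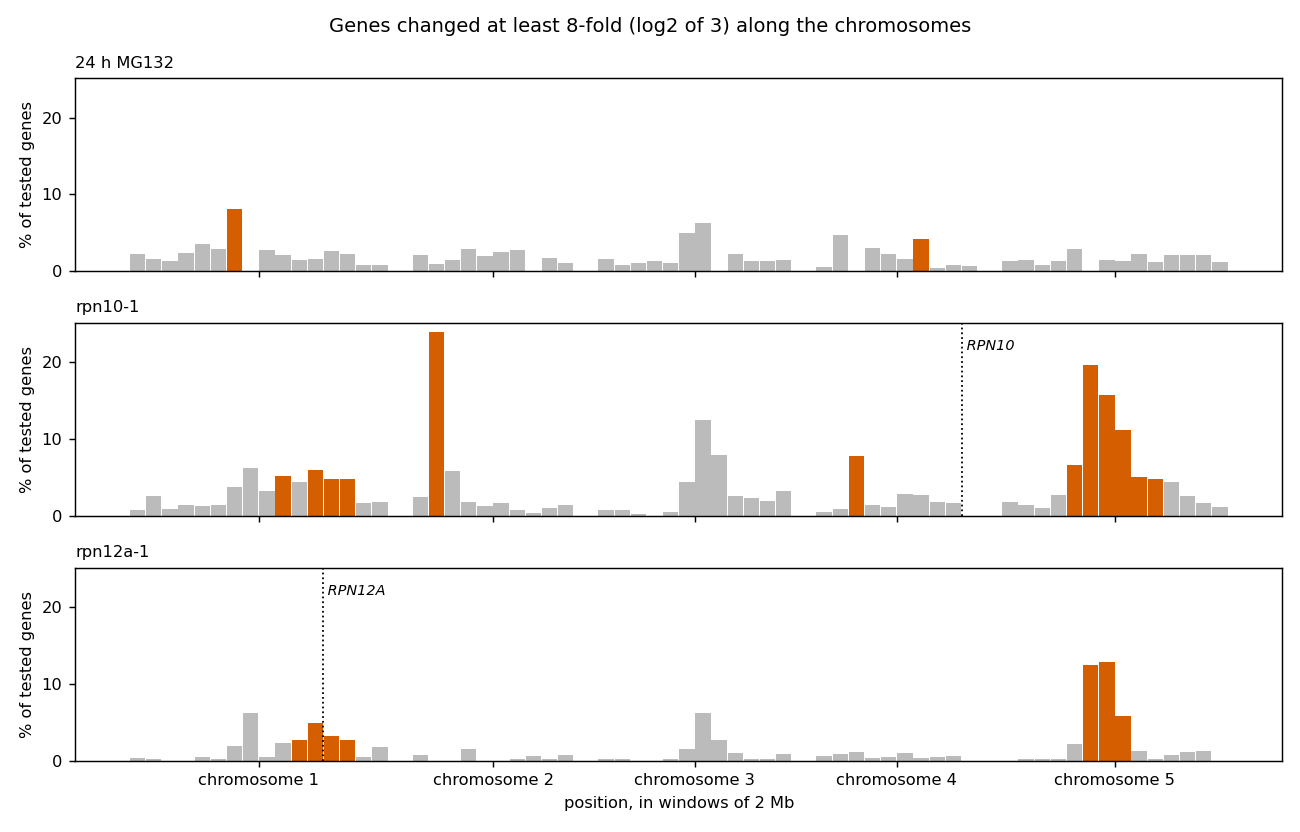
Percent of tested genes changed at least 8-fold (y axis) in each 2-Mb window along the 5 chromosomes (x axis) for 24 h of MG132, rpn10-1 and rpn12a-1; orange windows are enriched (one-sided Fisher exact test, adjusted p below 0.05), and dotted lines mark the mutated genes. 12 windows are enriched in rpn10-1, 7 in rpn12a-1 and 2 at 24 h of MG132.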

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

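Chosen after the results were seen were both tests of linkage to a mutated gene, the 3 tests of why more genes were called in rpn10-1, and the tests of depth and genotype for rpn10-1 replicate 1, the test of foreign DNA in both mutants and the splits at 3 h with the library set as a term; the test of the blocks against MG132 was set to count each gene once after a first look.

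RPN10 stood at 354 CPM in replicate 3 of the 3 h group, while the other 3 libraries lay between 296 and 300 CPM, a gap of 0.931 of the group's range. It was the only one of 30 groups of 4 values tested this way that passed, and chance alone passes about 1 in 20.

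Time of treatment turned the direction of some genes. Higher at 3 h and lower at 24 h than in untreated seedlings were 25 genes, and 16 were lower at 3 h and higher at 24 h; all of these were also called between 24 h and 3 h. Among the former, named here after their values were seen, were UGT74E2, an auxin glucosyltransferase gene, with log2 fold changes of 4.49 and -1.44, RNS1, a secreted ribonuclease gene, with 2.3 and -1.95, and the cold-induced KIN1 with 1.42 and -2.05. Among the latter were GRXS13, a glutaredoxin gene, with -2.18 and 0.98, and NAC6, a transcription factor gene of leaf ageing, with -0.85 and 0.98.

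Other splits of the 8 libraries of a comparison into 4 and 4 tested how often another split calls as many genes. At 24 h none did. The real split called 4261 genes in a fit of these 8 libraries and the highest of the other 34 called 81 (1 of 35). Between 24 h and 3 h none did either, with 1310 against 45 and again 1 of 35. At 3 h 2 of 35 called as many genes. The real split called 1951 and the split that follows the library set 2487, which points to a structure of the samples. With the library set as a term, under which that split cannot be fitted, no other split reached the real value at 3 h. The real split then called 4306 genes and the highest of the other 33 called 0 (1 of 34). These splits cannot exclude chance, as 1 of 35 or 1 of 34 is the lowest share they can give. The other splits also mix treated and untreated libraries, which widens the spread within their groups and lowers their counts. Within the sets 1228 genes (without the technical replicate note) and 4229 (with it) were called at 3 h.

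The changes of at least 8-fold in the mutants gathered in chromosome blocks, 12 windows in rpn10-1 and 7 in rpn12a-1, of which 6 were shared. The densest rpn10-1 window (chromosome 2, 2 to 4 Mb) held 26 such changes, all higher, and was not enriched in rpn12a-1. The tests below of MG132 and of foreign DNA in both mutants include its genes and were not run without them. A response to weaker proteasome function predicts that such genes move under MG132 as often inside blocks as outside, but 24% (59 of 246) did inside and 46.9% (161 of 343) outside (Fisher's exact test, p = 1.1e-08). DNA of another accession linked to the mutation was tested for rpn10-1 by the 372 genes within 1 Mb of RPN10. Of these, 1.34% had such a change (upper bound 3.11%, against at least 4.79% in each of the 12 windows). As large a share lay around 63.2% of tested genes. This argues against a block there as dense as those windows, which were picked for a high share. A shorter or sparser linked segment would escape this test and is not excluded. For rpn12a-1 linked DNA of another accession remains open for the windows near RPN12A. The share there was 5.76% of 382 genes, as large around 1.44% of tested genes. But rpn10-1 was enriched in the same windows without a mutation there. The same foreign DNA in both mutants remains a hypothesis, since in windows chosen on rpn10-1 alone 50% (112 of 224) of its changes were called the same way in rpn12a-1 and 27.5% (86 of 313) elsewhere, and in those chosen on rpn12a-1 alone 87.8% (72 of 82) and 71.8% (74 of 103; Fisher's exact test, p = 1.3e-07 and 0.011), though no sequence of the mutants was analysed.

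More genes were called in rpn10-1 (4873) than in rpn12a-1 (1039), a ratio of 4.69. Replicate 1 of rpn10-1 accounts for a part of this but not for all, since without it 2235 and 1203 genes were called (ratio 1.86), and without replicate 2 4483 and 1194 (ratio 3.75). The control libraries of each set may account for a part of it. Against the Col-0 libraries with the note, rpn10-1 gave 1854 and rpn12a-1 1389 (ratio 1.33). Against those without it they gave 5220 and 4598 (ratio 1.14). But in each ratio 1 mutant was set against libraries of the other set, so its count also holds the difference between sets. Each against its own set, rpn10-1 gave 5220 and rpn12a-1 1389. How much the controls account for was thus not separated. A stronger effect of rpn10-1 cannot be told apart from the spread between library sets by these counts, because each mutant was sequenced in 1 set only. Such an effect was also predicted to move the core particle list further in rpn10-1. Its median was 1.28 there and 1.77 in rpn12a-1, which goes the other way. The direct difference was not called with an estimated correlation (camera adjusted p = 0.93).

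Replicate 1 of rpn10-1 held counts in 2491 of the 6071 genes at 0 in all other libraries, none above 14. Depth is excluded, as 25692 genes had a count when it was thinned to 6646134 counts, against at most 23280 in the others. The genotype is excluded as the cause of the pattern: of the 6198 genes at 0 in all other groups, replicate 1 had a count in 1642 (lower bound 25.4%) and replicate 2 in 79 (upper bound 1.59%) at that depth. It stays open for a small part, as 47 had a count in both and, with replicate 1 set aside, the rpn12a-1 libraries had 58 and 50 of their own. Genomic DNA in the library is consistent with the counts per kb of exon in pseudogenes and transposon genes lying at 0.882 times those in protein-coding genes (95% bootstrap interval 0.817 to 0.955), and at that level would give 0.342% of the counts of the library.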

How the results depend on the processing

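Chosen after seeing the data were the fits restricted to nuclear protein-coding genes, to genes with a mean of at least 5 CPM or to positions outside the blocks, and those with other control libraries or another set for a mutant. The cause of the differences below was not tested unless it lies in fewer samples or genes or in the stricter threshold itself. The scaling by RLE and the fit of nuclear protein-coding genes left each of the 7 counts of called genes within 1.5 times of its value in the report. So did leaving out the blocks, for the 3 counts to which it was applied (rpn10-1, rpn12a-1 and genes higher in all 4). With a change of at least 2-fold required, the counts were 1358 at 3 h, 2040 at 24 h, 1346 between 24 h and 3 h, 2575 in rpn10-1 and 104 higher in all 4. Without a filter on low counts rpn12a-1 gave 1983 and the mutants against each other 3025; with a mean of at least 5 CPM rpn12a-1 gave 663. DESeq2 gave 2137 between the mutants. Without the library set term rpn10-1 gave 2735 and the mutants against each other 782, and with only these groups 261. From libraries without the note alone, 1228 genes were called at 3 h and 5469 between 24 h and 3 h; from those with it, 3633 at 24 h and 1923 between 24 h and 3 h. Against the Col-0 libraries of the other set, rpn10-1 gave 1854 and rpn12a-1 4598.

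The replicate numbers did not pair the libraries: correlations of same-numbered differences between groups ran from -0.188 to 0.2. With the replicate number as a block in place of the library set, rpn12a-1 gave 2124 genes, and no other count moved by over 1.5 times; the list calls it changed stand with rpn12a-1 and with the comparison of the mutants. Leaving out the library set term changed 5 list calls, given with 24 h, each mutant and the comparison of the mutants.

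Leaving out each library in turn gave 2666 to 4038 genes at 3 h, 3852 to 6317 at 24 h, 2008 to 4496 between 24 h and 3 h, 2235 to 5571 in rpn10-1, 495 to 1203 in rpn12a-1, 478 to 2045 between the mutants and 134 to 179 higher in all 4. The counts that moved by over 1.5 times were 2008, 2119 and 2185 between 24 h and 3 h (without 24 h replicate 1, 24 h replicate 2 and 3 h replicate 2), 2235, 3217 and 3076 in rpn10-1 (without its replicate 1 and Col-0 replicates 1 and 2), 564 and 495 in rpn12a-1 (without its replicates 1 and 2), and 521, 478, 804 and 2045 between the mutants (without rpn12a-1 replicates 1 and 2, rpn10-1 replicate 1 and 24 h replicate 1). With 1 library left in a mutant group, that library was assumed to vary like the other groups.

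With an estimated correlation 19 of the 57 list calls made with the preset one held. With split controls the correlations of 3 h and 24 h of MG132 with rpn10-1 were 0.137 and 0.119, and that of 24 h with rpn12a-1 was 0.177. Single named genes turned direction in these cases: ROF2 in rpn12a-1 (-0.86) stood at 0.24 with the replicate block and 0.19 against the other Col-0 libraries, LHCB4.3 in rpn10-1 (-1.57) at 0.15 with rpn10-1 placed in the other set and 0.23 against the other Col-0 libraries, and COR47 in rpn10-1 (1.06) at -0.14 with rpn10-1 placed in the other set. Leaving out a library gave -0.242 to 4.09 for AT5G66400, rpn10-1 (3.15), -0.458 to 4.15 for OLEO1, rpn10-1 (3.17) and -3.14 to 3.98 for CRU1, rpn10-1 (2.98), the lowest without rpn10-1 replicate 2 and the highest without replicate 1. Fits within a library set were not run for the genes higher in all 4 or for the mutants against each other, since each mutant lies in 1 set. Depth limits genes under a few CPM. Changes of 2-fold were recovered for 42% to 72% of the simulated genes, which were drawn from those above a minimum mean count.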

Other observations

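The gene families below were chosen and tested after the data were seen; both tests of TGGGC were set before their result, apart from the reading of the one for genes on no proteasome list.

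Grouping the tested genes by the product names of the annotation gave 409 families with at least 8 members, each tested for an excess of called genes (one-sided Fisher exact test, Benjamini-Hochberg adjusted over families). This test treats genes as independent, so its p-values are too small where members of a family vary together. The photosynthesis list, with an estimated correlation of 0.769 at 24 h, was not called once that was allowed for (camera adjusted p = 0.202). Nor was the early auxin list at 3 h (camera adjusted p = 0.187). At 3 h, families with an excess of lower genes included 24 of 62 SAUR genes, small auxin-induced genes of elongating tissue, where 5.73 were expected (adjusted p = 1.6e-07), 8 of 24 expansin genes (2.22 expected, adjusted p = 0.034) and 13 of 30 genes of the phototropic NPH family (2.77 expected, adjusted p = 0.00012). Higher were 10 of 32 for ubiquitin-conjugating enzymes (2.78 expected, adjusted p = 0.012) and 13 of 56 NAC genes (4.86 expected, adjusted p = 0.032). The NAC family stood out again at 24 h, with 21 of 56 higher (7.06 expected, adjusted p = 0.00011).

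At 24 h the families with an excess of higher genes included 17 of 31 cysteine-rich receptor-like kinase genes (3.91 expected, adjusted p = 4.6e-06), 20 of 48 WRKY genes (6.05 expected, adjusted p = 3.8e-05) and 34 of 115 disease resistance genes (14.5 expected, adjusted p = 7.6e-05). Of 10 genes with SPFH or band 7 domains, membrane proteins that include prohibitins, 9 rose (1.26 expected, adjusted p = 7.2e-06). All 10 photosystem I subunit genes fell (1.38 expected, adjusted p = 1e-06). In rpn10-1, 19 of 44 histone genes fell (5.08 expected, adjusted p = 4.6e-05) and 8 of 18 Mediator subunit genes rose (2.06 expected, adjusted p = 0.03).

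Some disease resistance genes were lower in the mutants. Of 203 genes lower in both mutants and not under MG132, 16 belonged to that family of 115, where 1.1 were expected (adjusted p = 7.3e-12). Of the 135 disease resistance genes found by the start of their product name, 3 were higher in both mutants and not under MG132. A chromosome block of either mutant held 15 of the 16 and a block of both held 8, while 74 of the 135 lay in a block of either. Foreign DNA shared by the mutants, for which 50% of the large changes of rpn10-1 in its blocks had the same direction in rpn12a-1, may account for the 8; this was not tested gene by gene. AT1G54040 (chromosome 1, 20170715 to 20173949, minus strand, TAIR10.1), the epithiospecifier gene that was higher in both mutants, lies in a window that was enriched in rpn12a-1 and not in rpn10-1. The windows on both sides of it (18 to 20 Mb and 22 to 24 Mb) were enriched in rpn10-1.

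A hypothesis on the genes higher in all 4 comparisons was that TGGGC, a core of sites reported for the NAC factors of this response, is frequent upstream of them. In the 500 bp upstream, on either strand, it occurred in 60.3% of the proteasome genes among them (35 of 58; exact 95% interval 46.6 to 73), against a median of 43.1% and a 95th percentile of 53.4% in 10000 random lists matched on expression (p = 0.0042 over these lists). It ranked 4 of 512 among words of that length, behind CGGGC, GGCCC and AGCCC. The random lists were matched on expression and not on base composition, so GC-rich words in general were not told apart from TGGGC. Among the genes on no proteasome list it occurred in 41.7% (48 of 115; exact 95% interval 32.6 to 51.3), against a median of 36.5% and a 95th percentile of 43.5% (p = 0.13 over such lists), which leaves the question open for them. The motif, or GC-rich words like it, may thus mark the proteasome genes, but a link to NAC053 or NAC078 was not measured in these libraries.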
